A study of Homo sapiens with 9 samples.

How the data were processed

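Gene expression was measured by sequencing of polyadenylated RNA from 9 samples of SF8628, an established line from a diffuse intrinsic pontine glioma (a childhood tumour of the brainstem). Per the labels' protocols, 500000 cells in DMEM were treated for 6 h with 1% DMSO or with CDDO-2P-Im at 0.3 or 0.7 µM, RNA was extracted with a PureLink kit, and libraries were made with a TruSeq stranded mRNA kit. A DMSO level was found for the control group only. A difference in DMSO between treated and control cells therefore cannot be told apart from the compound. Groups and replicate numbers were taken from the sample labels, with 3 libraries per group. Nothing in the sources used here states that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

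The submitters' processing notes name cutadapt, HISAT2, StringTie and edgeR without versions. The genome build and the strand setting of the counting are not given in the sources used here. Of the 33510 gene IDs, 32499 are also in GENCODE release 29, whose coordinates are those of GRCh38, and 86.9% of these have its start or end, so coordinates are given as the deposited table lists them and are taken to be GRCh38. The deposited table gives, per gene and library, an expected count that the authors derived from the assembled transcripts, and an FPKM value (fragments per kilobase of transcript, relative to the mapped fragments) that the authors normalised for gene length and depth. All counts were whole numbers, no gene was at 0 in every library, and the FPKM values of both deposited sheets were identical in all 301590 cells. Counts from 4 to 23 were multiples of 4 in 39.5% of cases against 25% with no step, so that 1 sequenced fragment appears to enter as about 4 counts. No per-sample column was left unused.

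The main test was edgeR 4.0.16 in R 4.3.3 on the deposited expected counts, with TMM scaling, the default expression filter (minimum count 10, minimum total 15), a quasi-likelihood F test with the group as the only term, all 9 libraries in 1 fit, and Benjamini-Hochberg adjustment over the 21026 genes that passed the filter. Genes with an adjusted p under 0.05 are described as changed. The standard error of a log2 fold change was taken as its size divided by the square root of F. Tests were two-sided. Each of the 3 comparisons between the groups was made. Group levels are given as mean ± SD of the deposited FPKM, with n = 3 in each group. A fold against a group at 0 in all 3 libraries was taken against a floor of 12 counts, or about 3 fragments, over that group. The floor covers counting error of that group only, not of the treated libraries. It was set after the step in the counts was seen.

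The 27 gene lists (678 entries) were fixed before the data were examined: NRF2 targets, heat shock (HSF1), integrated stress response (ATF4) and ER unfolded protein response genes, mitochondrial proteases and chaperones, nuclear OXPHOS subunits, mitochondrially encoded mRNAs, proteasome subunits, cholesterol synthesis, S phase, G2 and M phase, p53 target, apoptosis, NF-kB, JAK-STAT3 and immediate early genes, metallothioneins and zinc transport, hypoxia and glycolysis, TGF-beta and extracellular matrix, interferon-stimulated, and autophagy and lysosome genes, markers of oligodendrocyte precursors, astrocytes, neurons, mesenchymal and stromal cells, and immune and endothelial cells, and replication-dependent histones. For each list, changed members were counted with adjustment over all genes and with adjustment over the list alone, and the list was tested against all other genes with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01), adjusted over the 27 lists of a comparison, and again with an estimated correlation. Genes were named by a rule fixed at the same time: NFE2L2, KEAP1 and LONP1; for each dose against DMSO, the 10 largest rises and 10 largest falls among changed genes with a mean of at least 1 FPKM in the higher group, no overlap between groups and a symbol that is not a clone, LOC, LINC or antisense identifier; the 6 largest each way between the doses; and up to 4 members per list with the smallest p. Not every gene that the rule gives is printed. Genes plotted per replicate, some list members outside this rule that are named because 5 or fewer of a list moved in that direction, and further genes said to be so were chosen after their values were seen.

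The fits were tested on simulated data drawn with the measured means, dispersions and library sizes, with 200 genes changed per dose. A simulated log2 change of 1 was recovered for 56.2% of genes at 0.3 µM against DMSO, 55.8% at 0.7 µM and 59.2% between the doses, and a change of 2 for 67.4%, 72.6% and 72.2%. False calls made up 4.13%, 7.58% and 5.34% of calls. Far fewer genes changed in the simulation than were called in the data. The adjusted threshold was therefore stricter there, and these shares need not hold for the data. Because both doses were set against the same DMSO libraries, 20 sets of unchanged groups were simulated in which both doses shared the simulated DMSO libraries. All 9 libraries of a set were drawn anew from the mean over all measured libraries. Terms of the gene ontology listed in the deposited table were tested with a one-sided Fisher's exact test over the 12627 tested genes with GO terms in the table used here (1513 terms of 15 to 500 genes). Part of the ontology entries in that table hold removed text, so terms are missing there and the counts for the affected terms are incomplete.

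Alternatives to the main test were DESeq2 1.42.0, RLE factors, library size alone, limma-voom, limma-trend on log2(FPKM + 1) of genes at 1 FPKM or more in at least 3 libraries, no expression filter beyond 1 count, a filter at 1 CPM in at least 3 libraries, a fit of only the 6 libraries compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and each library left out in turn. Counts divided by 4 were added as an alternative after the data had been seen. Intervals are at 95% and, where they come from resampling, use 10000 draws. Counts of genes with near-identical copies or overlapping neighbours (HSPA1A and HSPA1B, HSPA6 and HSPA7, FAM47E-STBD1, microRNA genes) are uncertain, since the authors' counting could divide shared reads between them, and so are counts of antisense genes. Plots were drawn with matplotlib 3.10.9.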

Results

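RNA was sequenced from SF8628 cells, a line from a diffuse intrinsic pontine glioma, after 6 h with 1% DMSO or with CDDO-2P-Im at 0.3 or 0.7 µM. CDDO-2P-Im is a synthetic oleanane triterpenoid imidazolide, and compounds of this class are known to act on KEAP1, the repressor of the transcription factor NRF2, and on the mitochondrial protease LONP1. Each group had 3 libraries, 9 in all. Total expected counts ran from 76710679 to 86312823 per library, at about 4 counts per fragment. Between 23859 and 24067 genes had a count in the DMSO libraries, 24109 to 24379 at 0.3 µM and 25120 to 25679 at 0.7 µM. Mitochondrial genes took a mean of 5.31% of counts in DMSO, 4.35% at 0.3 µM and 3.85% at 0.7 µM (n = 3). The first principal component of log2 CPM held 29.6% of the variance and placed the DMSO libraries between -72.4 and -70.4, those at 0.3 µM between 0.0035 and 9.68, and those at 0.7 µM between 61.2 and 69.3. Replicate 1 at 0.7 µM stood apart from the other libraries of its group, with a mean chi-square per gene of 33.2 against replicate 2 and 22.7 against replicate 3. All other pairs of replicates lay between 4.12 and 7.71, and no pair was as close as sampling noise of fragments allows, a mean of 1.

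The known regulators and targets of the compound class were compared first. NFE2L2 (ENSG00000116044, chromosome 2, 177227595 to 177287777), which encodes NRF2, had 26.6 ± 0.0847 FPKM in DMSO (mean ± SD, n = 3, as for all values of this kind), 40.4 ± 1.40 at 0.3 µM and 51.2 ± 1.36 at 0.7 µM, and rose at both doses (log2 fold change 0.67, SE 0.05, edgeR adjusted p = 3.0e-06, and 1.03, SE 0.05, adjusted p = 4.5e-08). KEAP1 (ENSG00000079999, chromosome 19, 10486125 to 10503356) rose at 0.3 µM, from 23.9 ± 0.558 to 28.9 ± 1.05 FPKM (log2 fold change 0.34, adjusted p = 0.0040). It had 20.7 ± 1.84 FPKM at 0.7 µM (-0.12 against DMSO, adjusted p = 0.204) and was lower at 0.7 than at 0.3 µM (-0.46, adjusted p = 9.3e-04). LONP1 (ENSG00000196365, chromosome 19, 5691834 to 5720572) had 24.7 ± 0.953 FPKM in DMSO and 25.9 ± 1.72 at 0.3 µM (0.14, adjusted p = 0.217), and rose to 38.0 ± 2.77 at 0.7 µM (0.71, SE 0.07, adjusted p = 1.1e-05).

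At 0.3 µM, cells raised genes of the NRF2 and heat shock responses within 6 h and lowered genes of the cell cycle. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35390293), haem oxygenase 1, rose 116-fold, from 19.9 ± 2.03 to 2190.4 ± 99.8 FPKM (log2 fold change 6.85, SE 0.09, adjusted p = 3.7e-12). HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526894), a stress-inducible HSP70, rose from 1.27 ± 0.402 to 137 ± 31.4 FPKM (6.81), and HSPA1A (ENSG00000204389, chromosome 6, 31815543 to 31817946), the main inducible HSP70, from 71.9 ± 1.91 to 2326 ± 297 FPKM (5.09). The pseudogene HSPA7 (7.21) and HSPA1B (4.96) moved with them, and counts of these near-identical pairs cannot be assigned with certainty. ZFAND2A, an arsenite-inducible zinc finger protein (3.61), and the HSP40 co-chaperone DNAJA4 (3.46) were also among the 10 largest rises. TNFSF18, the ligand of GITR, rose from 1.06 ± 0.109 to 14.9 ± 0.569 FPKM (3.87) and NRCAM, a neuronal cell adhesion molecule, from 0.339 ± 0.0571 to 3.43 ± 0.193 FPKM (3.40). The T-cell receptor orphon TRBV20OR9-2 (4.46) rested on 5, 4 and 0 counts in the DMSO libraries.

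Among the 10 largest falls at 0.3 µM, TNFSF15 (ENSG00000181634, chromosome 9, 114784652 to 114806039), a TNF superfamily ligand, fell from 2.63 ± 0.0931 to 0.157 ± 0.0308 FPKM (log2 fold change -3.98, SE 0.24, adjusted p = 6.4e-07). TNFSF11, which encodes RANKL, was lower by a log2 fold change of -2.76. MEOX2 (ENSG00000106511, chromosome 7, 15611212 to 15686683), a homeobox transcription factor, fell from 19.7 ± 1.67 to 3.16 ± 0.321 FPKM (-2.57), and THBD, thrombomodulin, from 13.4 ± 0.760 to 2.11 ± 0.216 FPKM (-2.59). RASD2 (-3.01), the Frizzled-4 ligand NDP (-2.94), GAS1 (-2.65), ESM1 (-2.60) and the cytokine signalling suppressor SOCS1 (-2.59) were also among the 10 largest falls.

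Of 39 tested NRF2 targets, 32 rose at 0.3 µM, 0 fell and 7 did not pass (36 and 0 adjusted over the list alone). Besides HMOX1, these included OSGIN1 (4.44 ± 0.0873 to 36.3 ± 1.55 FPKM, log2 fold change 3.10), GCLM, the modifier subunit of the first enzyme of glutathione synthesis (22.4 ± 1.01 to 112 ± 4.34 FPKM, 2.40), and the sulfiredoxin SRXN1 (101 ± 3.92 to 366 ± 11.9 FPKM, 1.92). Of 28 heat shock genes, 27 rose and 0 fell (27 and 0 adjusted over the list alone), among them DNAJB4 (2.46) and the constitutive chaperone HSPA8 (1.38). Of 34 integrated stress response genes, 23 rose and 2 fell (26 and 2 adjusted over the list alone). The ATF4 transcript itself rose (0.97), as did CHAC1, which degrades glutathione (2.63), and the mitochondrial folate enzyme MTHFD2 (0.65), whereas STC2 (-1.05) and the transcription factor CEBPB (-0.93) fell. Of 33 proteasome genes, 26 rose and 1 fell (28 and 1 adjusted over the list alone), with PSMD12 at 0.64, PSMD11 at 0.65 and PSMC2 at 0.60. The gene that fell was NFE2L1 (-0.30), a transcription factor of proteasome genes and not a subunit. With library size as the only scaling, 17 proteasome genes rose. Of 28 autophagy and lysosome genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone), led by the cathepsin CTSL (1.55), the receptor SQSTM1 (1.47) and GABARAPL1 (1.43). WIPI1 (-0.69), NBR1 (-0.38) and BECN1 (-0.19) fell. Of 28 hypoxia and glycolysis genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone), with the prolyl hydroxylase EGLN3 at 2.07 and the collagen hydroxylase P4HA1 at 0.88, and PFKFB4 (-1.26) and the lactate exporter SLC16A3 (-0.36) lower. Of 30 immediate early genes, 11 rose and 7 fell (13 and 7 adjusted over the list alone), with JUN at 1.49 and EGR1 at 1.07.

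Cell cycle genes moved the other way. Of 32 S phase genes, 25 fell and 0 rose at 0.3 µM (27 and 0 adjusted over the list alone), including the methylation maintenance factor UHRF1 (log2 fold change -1.31), the replication licensing factor CDC6 (-0.72) and the ribonucleotide reductase subunit RRM2 (-0.59). Of 33 G2 and M phase genes, 28 fell and 0 rose (33 and 0 adjusted over the list alone), including the mitotic kinases AURKB (-1.10) and PLK1 (-0.82). Of 13 mitochondrially encoded mRNAs, 11 fell and 0 rose (12 and 0 adjusted over the list alone), with MT-ND2, a subunit of complex I, at -0.74 and MT-ND1 at -0.50. Of 24 NF-kB and inflammatory genes, 12 fell and 3 rose (13 and 4 adjusted over the list alone). The inhibitor of apoptosis BIRC3 (-2.47) and the co-regulator BCL3 (-2.14) fell, and the chemokines CXCL2 (2.09) and CXCL3 (0.99) and the cyclooxygenase PTGS2 (adjusted p = 1.7e-04) rose. Of 25 interferon-stimulated genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with OASL at -0.95 and the RNA sensor DDX58 at -1.05, and IFITM1 higher (0.25). Of 29 TGF-beta and extracellular matrix genes, 12 fell and 3 rose (13 and 4 adjusted over the list alone), with the signal transducer SMAD3 at -1.07 and COL1A1 at -0.55, and CCN2 (0.52), POSTN (0.44) and TGFBI (0.34) higher.

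The camera calls for NRF2 targets (adjusted p = 5.54e-37), heat shock genes (6.68e-42), S phase genes (5.29e-15) and G2 and M phase genes (1.55e-18) at 0.3 µM held with an estimated correlation, at adjusted p = 0.00262, 0.0344, 0.0253 and 0.0344. Those for the ATF4, mitochondrially encoded, proteasome and hypoxia lists did not, at adjusted p = 0.184, 0.147, 0.147 and 0.0831 with an estimated correlation. Nor did those for the NF-kB, interferon, autophagy, TGF-beta and immediate early lists, at adjusted p = 0.0568, 0.0916, 0.0568, 0.298 and 0.432 with an estimated correlation.

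Of 27 ER unfolded protein response genes, 3 rose and 3 fell at 0.3 µM (3 and 3 adjusted over the list alone), with the sensor kinase ERN1 (0.89), DNAJB9 (0.42) and CANX (0.22) higher and EDEM1 (-0.37), PDIA4 (-0.30) and SEC24D (-0.25) lower. With library size as the only scaling, 1 of them rose and 7 fell. SEC24D lost its call without DMSO replicate 1 or 2 or 0.3 µM replicate 3, at adjusted p = 0.0622, 0.0537 and 0.0587. Of 24 mitochondrial proteases and chaperones, 4 rose and 0 fell (4 and 0 adjusted over the list alone), all of them chaperones or their cofactors, HSPD1 (1.19), HSPE1 (0.95), HSPA9 (0.41) and GRPEL1 (0.34). Of 43 nuclear OXPHOS genes, 0 rose and 3 fell (0 and 1 adjusted over the list alone), with CYC1 at -0.28 and ATP5F1A at -0.18, and with library size as the only scaling 6 fell. The call of CYC1 was lost without any single DMSO or 0.3 µM library and with no expression filter (adjusted p 0.0011 to 0.137 over the alternatives). That of ATP5F1A was lost in settings that included leaving out any single DMSO library or 0.3 µM replicate 1 or 3 (0.0033 to 0.119 over the alternatives). Of 25 cholesterol synthesis genes, 4 rose and 2 fell (4 and 4 adjusted over the list alone), with CYP51A1 at 0.26, ACAT2 at -0.39 and MVK at -0.47, and with library size as the only scaling 3 rose and 6 fell. Of 26 p53 targets, 8 rose and 2 fell (8 and 4 adjusted over the list alone), with the cell cycle inhibitor CDKN1A at 1.17 and PHLDA3 at -0.67 and BBC3 at -1.38, and with library size as the only scaling 6 rose and 4 fell. Of 29 apoptosis regulators, 6 rose and 7 fell (7 and 7 adjusted over the list alone), with the survival factor BCL2L1 at -0.61. Of 22 JAK-STAT3 genes, 7 rose and 10 fell (8 and 11 adjusted over the list alone), with the kinase PIM1 at 1.75 and the cyclin CCND1 at -1.22. Of 10 genes for metallothioneins and zinc transport, 1 rose and 0 fell (1 and 0 adjusted over the list alone), the zinc exporter SLC30A1 (1.86).

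Among marker lists at 0.3 µM, 0 of 6 tested oligodendrocyte precursor markers rose and 2 fell (0 and 2 adjusted over the list alone), CSPG4 (-0.70) and VCAN (-1.01). Of 12 astrocyte markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with SLC1A3 at 0.65, GJA1 at 0.53, CLU at 0.44 and SOX9 at -0.90. Of 9 neuron markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone). The neurofilament gene NEFM, with 0 counts in DMSO and 49 at 0.3 µM, was 4.36-fold above the floor set for DMSO, and SYT1 was lower (-0.59). Of 15 mesenchymal and stromal markers, 1 rose and 6 fell (3 and 6 adjusted over the list alone), with PDGFRB at -0.44 and VIM at -0.32, and S100A4 higher (0.26). Of 8 immune and endothelial markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone), led by PECAM1 (6.14 ± 0.269 to 2.21 ± 0.0961 FPKM, log2 fold change -1.40). The others, CSF1R (-0.87) and KDR (-3.04), lost their calls. This happened to CSF1R in settings that included no expression filter and leaving out DMSO replicate 1 or 2 or 0.3 µM replicate 1 or 2 (adjusted p 0.0094 to 0.101 over the alternatives). It happened to KDR in limma-voom, with no expression filter, without any single DMSO library, without 0.3 µM replicate 2 or 3 or without 0.7 µM replicate 2 or 3 (0.0018 to 0.141 over the alternatives). Of 8 listed histone genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone). The camera calls for the immune and endothelial and the histone lists were lost, at adjusted p = 0.146 and 0.352 with an estimated correlation.

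In total, 4189 of 21026 genes changed at 0.3 µM in edgeR's quasi-likelihood test, 2062 higher and 2127 lower, and 787 of them by at least 2-fold, 454 higher and 333 lower. This number depends on the spread shared with the 0.7 µM libraries. In fits of only the 6 libraries compared, 5495 genes changed at 0.3 µM and 6603 at 0.7 µM. The 3 treated libraries lay entirely above or below the 3 DMSO libraries for 40.3% of tested genes, against 10% by chance. With library size as the only scaling, 35.8% of the calls were higher, and on log2(FPKM + 1) 33.6%, against 49.2% in the main test.

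**Figure D1:**
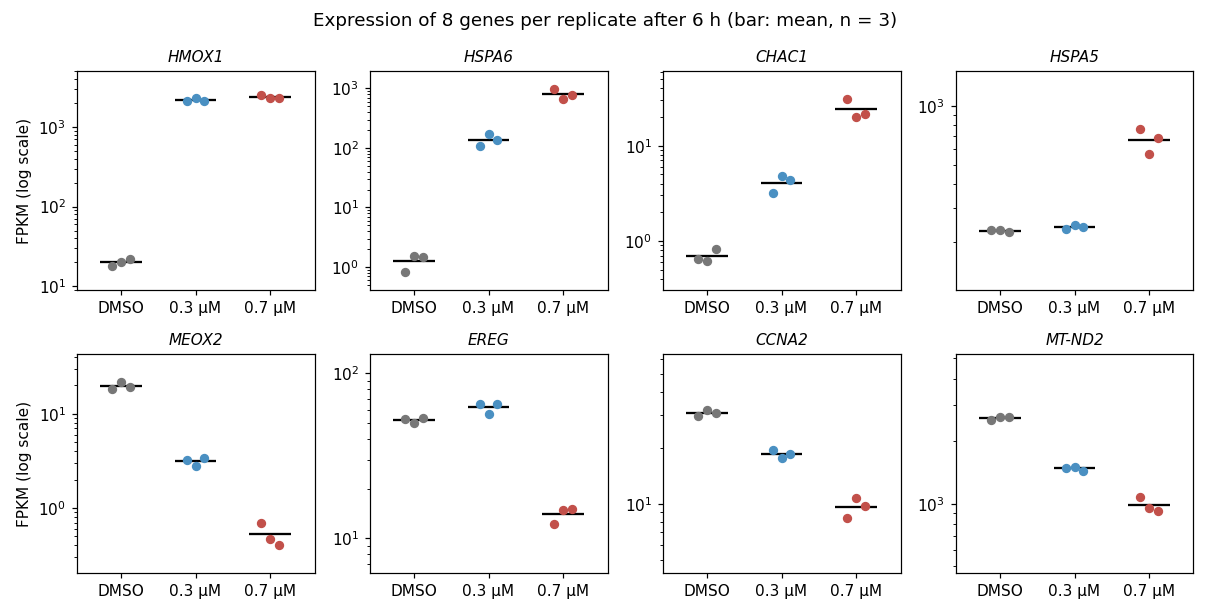
FPKM on a log scale (y axis) of 8 genes in each of the 3 libraries (points) with DMSO, 0.3 and 0.7 µM CDDO-2P-Im (x axis), with the group mean as a bar. HMOX1 had a mean of 2190.4 FPKM at 0.3 µM and did not pass the test between the doses, while HSPA6, CHAC1 and HSPA5 were higher at 0.7 than at 0.3 µM and MEOX2, CCNA2 and MT-ND2 were lower, and EREG was higher than DMSO at 0.3 µM and lower at 0.7 µM.

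At 0.7 µM genes of the heat shock and integrated stress responses rose, while TGF-beta and extracellular matrix, interferon-stimulated and cell cycle genes fell. HSPA6 reached 809 ± 169 FPKM, 670-fold above DMSO (log2 fold change 9.39, SE 0.31, adjusted p = 2.8e-09), and HSPA7 98.5 ± 21.2 FPKM (9.87). HMOX1 had 2390.0 ± 135 FPKM, 128-fold above DMSO (adjusted p = 3.1e-12). HSPA1A (6.03), HSPA1B (5.89), ZFAND2A (5.28) and DNAJA4 (4.93) were again among the 10 largest rises. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956512) joined them at 24.0 ± 5.75 FPKM against 0.691 ± 0.115 in DMSO (5.19, SE 0.23, adjusted p = 2.1e-08). TRBV20OR9-2 (5.11) had 154, 60 and 94 counts. The microRNA gene MIR222 had 0 counts in DMSO and 12, 11 and 15 counts at 0.7 µM, 3.32-fold above the floor set for DMSO. MEOX2 fell to 0.522 ± 0.155 FPKM (-5.14, SE 0.19, adjusted p = 5.1e-09). The oxysterol receptor GPR183 fell from 13.4 ± 0.982 to 0.764 ± 0.133 FPKM (-4.04), and among the 10 largest falls were also TNFSF11 (-4.22), TNFSF15 (-4.09), NDP (-3.83), THBD (-3.25) and SERTAD4 (-3.09). INKA1 (-3.28) had 72, 8 and 8 counts in its 3 libraries. PP7080 (-6.61) varied between 128 and 768 counts in the DMSO libraries and lost its call in limma-voom, at adjusted p = 0.174 (2.3e-08 to 0.174 over the alternatives).

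Of 39 NRF2 targets, 30 rose and 3 fell at 0.7 µM (31 and 3 adjusted over the list alone), with OSGIN1 at 2.82 and SRXN1 at 1.98, and AKR1C2, an aldo-keto reductase, lower (-0.99), as were UGDH (-0.30) and TKT (-0.15). Of 28 heat shock genes, 27 rose and 0 fell (27 and 0 adjusted over the list alone), with HSPA4L at 3.90 and DNAJB1 at 4.47. Of 34 integrated stress response genes, 32 rose and 0 fell (32 and 0 adjusted over the list alone), including the asparagine synthetase ASNS (8.55 ± 0.537 to 43.1 ± 2.74 FPKM, log2 fold change 2.42), the transcription factor CEBPG (2.08) and the glycyl-tRNA synthetase GARS1 (1.74). Of 27 ER unfolded protein response genes, 12 rose and 3 fell (13 and 4 adjusted over the list alone). The ER chaperone HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241343) rose from 229 ± 2.25 to 671 ± 97.0 FPKM (1.64, SE 0.09, adjusted p = 8.2e-08), and HERPUD1 (2.92), DNAJB9 (1.69) and ERN1 (1.57) rose too. The genes EDEM1 (-0.39), EDEM2 (-0.39) and SEC24D (-0.21) fell. With library size as the only scaling, 10 of the list rose and 5 fell. Of 33 proteasome genes, 31 rose and 0 fell (32 and 0 adjusted over the list alone), with PSMD12 at 0.82. Of 25 cholesterol synthesis genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with the lanosterol demethylase CYP51A1 at 0.84 and the regulator SREBF2 at 0.45. Of 28 autophagy and lysosome genes, 18 rose and 3 fell (18 and 3 adjusted over the list alone), with SQSTM1 at 1.87, GABARAPL1 at 1.68 and CTSL at 0.91, and WIPI1 (-0.45), NBR1 (-0.55) and BECN1 (-0.21) lower. The counts were 16 and 5 with library size as the only scaling. Of 28 hypoxia and glycolysis genes, 16 rose and 5 fell (18 and 6 adjusted over the list alone), with VEGFA at 1.46 and the hexokinase HK2 at -1.34, and PFKFB4 (-0.91), LDHA (-0.42), SLC16A3 (-0.27) and PKM (-0.16) lower.

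Of 32 S phase genes, 27 fell and 1 rose at 0.7 µM (29 and 1 adjusted over the list alone), with UHRF1 at -1.85, RRM2 at -1.25 and PCNA, the polymerase clamp, at -0.98, and the histone mRNA binding protein SLBP higher (0.61). Of 33 G2 and M phase genes, 31 fell and 0 rose (31 and 0 adjusted over the list alone), with the cyclin CCNA2 going from 30.8 ± 1.10 to 9.63 ± 1.16 FPKM (log2 fold change -1.59, SE 0.09, adjusted p = 9.1e-08), KIF20A at -1.30 and PLK1 at -1.29. Of 29 TGF-beta and extracellular matrix genes, 22 fell and 1 rose (25 and 1 adjusted over the list alone), with SMAD3 at -1.43, COL1A1 at -0.79 and SPARC at -0.72. FN1, chosen after its values were seen, had 1132 FPKM in replicate 1 and 1662 and 1493 in the other libraries. Of 25 interferon-stimulated genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone), with OAS2 at -1.43, OAS3 at -1.28 and IFIT1 at -1.21, and IRF1 higher (0.49). Of 15 mesenchymal and stromal markers, 9 fell and 0 rose (9 and 0 adjusted over the list alone), with PDGFRB at -0.95 and CD44 at -0.53.

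Camera calls at 0.7 µM for NRF2 targets (adjusted p = 8.09e-17), heat shock (6.47e-32), ATF4 (1.28e-26), S phase (8.24e-13), G2 and M phase (2.70e-20), TGF-beta (4.85e-12), interferon (6.44e-10), autophagy (1.25e-06) and mesenchymal genes (8.97e-05) held with an estimated correlation, NRF2 targets at adjusted p = 0.0251 and the others at 0.0345. Those for the ER unfolded protein response, mitochondrially encoded, proteasome, cholesterol and hypoxia lists did not, at adjusted p = 0.103, 0.103, 0.132, 0.176 and 0.182 with an estimated correlation. Leaving out replicate 1 at 0.7 µM gave 7563 changed genes against 7281.

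The mitochondrially encoded mRNAs fell together at 0.7 µM, 13 of 13 (13 adjusted over the list alone). MT-ND2 (ENSG00000198763, mitochondrial genome, 4470 to 5511) fell from 2590.0 ± 50.3 to 985 ± 81.3 FPKM (log2 fold change -1.31, SE 0.06, adjusted p = 2.0e-08), MT-CYB from 1313 ± 41.0 to 623 ± 28.9 FPKM (-0.99) and MT-CO3 from 5366 ± 120 to 2883 ± 144 FPKM (-0.81). The mitochondrial rRNAs, chosen for comparison after their values were seen, were higher, MT-RNR1 by 0.50 (adjusted p = 2.9e-04) and MT-RNR2 by 0.30 (adjusted p = 8.9e-04). Of 43 nuclear OXPHOS genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), with SDHA, a subunit of complex II, at -0.57 and NDUFA10 at 0.26, and with library size as the only scaling 0 rose and 10 fell. Of 24 mitochondrial proteases and chaperones, 6 rose and 5 fell (6 and 5 adjusted over the list alone), with HSPD1 at 1.51, HSPE1 at 1.45, HSPA9 at 0.95 and LONP1 at 0.71, and PMPCA (-0.31), CLPX (-0.27), AFG3L2 (-0.26), STOML2 (-0.23) and PITRM1 (-0.21) lower; with library size as the only scaling 6 rose and 8 fell.

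**Figure D2:**
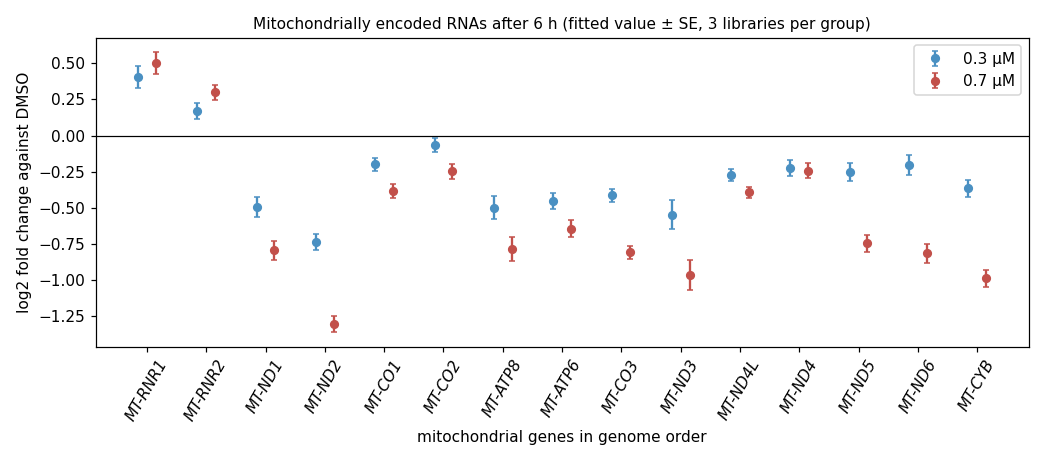
Fitted log2 fold change against DMSO (y axis, points with SE bars, 3 libraries per group) of mitochondrially encoded RNAs in genome order (x axis) at 0.3 and 0.7 µM. The rRNAs MT-RNR1 and MT-RNR2 lay above 0 and all 13 mRNAs below 0, with MT-ND2 at -1.31 at 0.7 µM; MT-CO2 and MT-ND6 did not pass the test at 0.3 µM.

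Lists with changes in both directions at 0.7 µM included p53 targets, of which 5 rose and 8 fell of 26 (6 and 8 adjusted over the list alone), with GADD45A at 1.65, the death receptor TNFRSF10B at 1.34, CDKN1A at 1.22, MDM2 at 0.44, PPM1D at 0.42 and the repair factor XPC at -0.95. Of 29 apoptosis regulators, 9 rose and 10 fell (9 and 10 adjusted over the list alone), with the BH3-only gene PMAIP1 at 0.83, FADD at -0.97 and BCL2L1 at -0.80. Of 24 NF-kB genes, 8 rose and 8 fell (8 and 8 adjusted over the list alone), with CXCL2 at 4.59, PTGS2 at 1.17 and BIRC3 at -1.70. Of 22 JAK-STAT3 genes, 7 rose and 10 fell (8 and 10 adjusted over the list alone), with PIM1 at 1.78 and CCND1 at -0.92. Of 30 immediate early genes, 11 rose and 7 fell (12 and 7 adjusted over the list alone), with IER5 at 2.88, JUN at 1.97 and the phosphatase DUSP6 at -1.43. Of 10 metallothionein and zinc transport genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with SLC30A1 at 2.03, MT1X at 0.78, MT1E at 0.36 and the zinc importer SLC39A10 at -0.62, besides MT1F (adjusted p = 0.0099). Of 6 oligodendrocyte precursor markers, 4 fell and 0 rose (4 and 0 adjusted over the list alone), CSPG4 (-1.18), GPR17 (-1.18), VCAN (-1.80) and PDGFRA (-1.72). The camera call for these markers was lost, at adjusted p = 0.181 with an estimated correlation. Of 12 astrocyte markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with GFAP at 1.72, CLU at 1.43, SLC1A3 at 0.81, ALDOC at 0.41, GJA1 at 0.27, APOE at -0.38 and SOX9 at -1.34. With library size as the only scaling, 3 rose and 2 fell. Of 9 neuron markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone), TUBB3 (0.88) and NEFM, 10.3-fold above the floor set for DMSO from 118 counts. Of 8 immune and endothelial markers, 2 fell and 0 rose (2 and 0 adjusted over the list alone), PECAM1 (-1.85) and CD68 (-0.57), and of 8 histone genes 1 fell and 0 rose (1 and 0 adjusted over the list alone). CD68 lost its call without DMSO replicate 1 or 2, at adjusted p = 0.0627 and 0.171, without 0.3 µM replicate 3, at 0.0513, and without 0.7 µM replicate 3, at 0.135. It also did so with no expression filter, at 0.0700, and with only the 6 libraries compared, at 0.0626 (0.0093 to 0.171 over the alternatives).

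In total, 7281 genes changed at 0.7 µM, 3477 higher and 3804 lower, and 1963 by at least 2-fold, 1269 higher and 694 lower. The groups did not overlap for 46.3% of tested genes, against 10% by chance. On log2(FPKM + 1), 32.9% of the calls were higher, against 47.8% in the main test. Protein-coding genes were called higher in 2712 cases and lower in 3631, and long non-coding genes higher in 548 cases and lower in 108 of 3872 tested, including antisense genes, whose reads could come from the other strand.

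**Figure D3:**
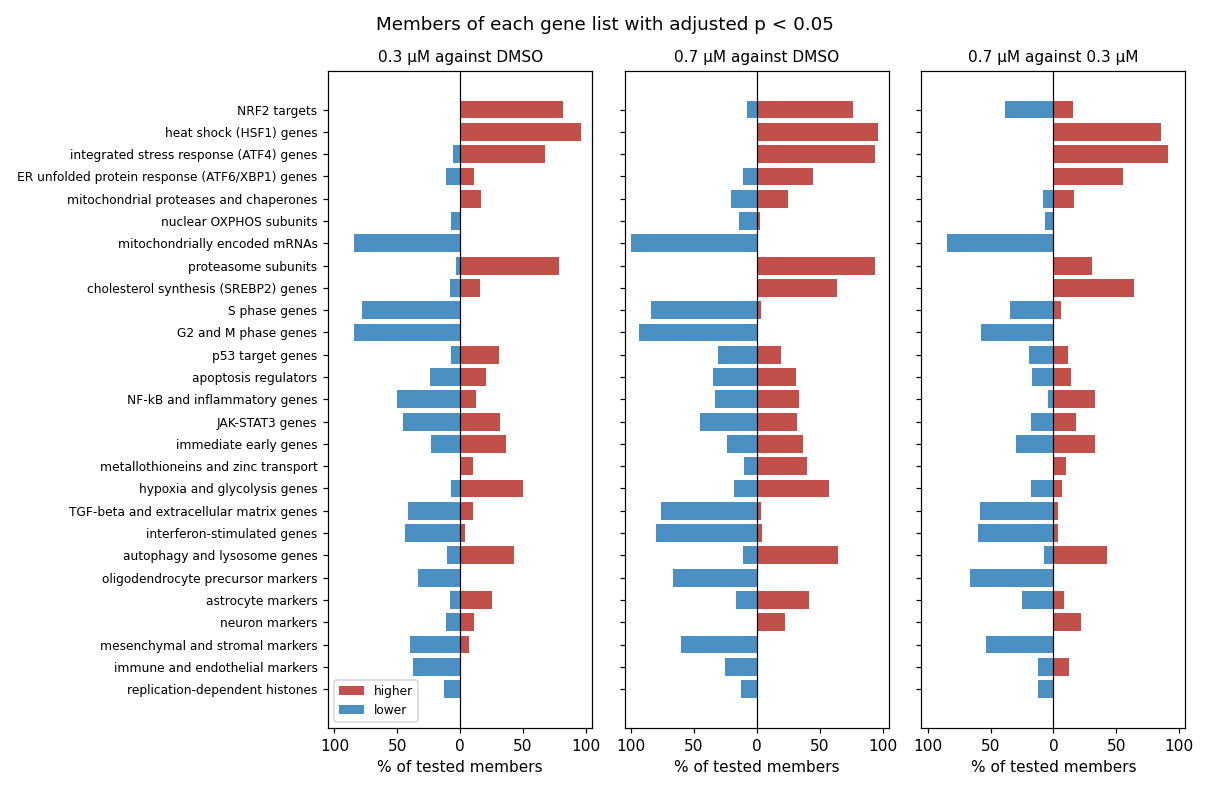
Share of the tested members of each gene list (y axis) called higher (right of 0) or lower (left of 0) in each comparison, in percent of tested members (x axis). Heat shock genes were called higher in 27 of 28 cases at both doses, and integrated stress response genes in 23 of 34 at 0.3 µM and 32 of 34 at 0.7 µM.

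Between the doses, DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737), the transcription factor CHOP, rose from 20.1 ± 3.75 FPKM at 0.3 µM to 151 ± 38.2 at 0.7 µM (log2 fold change 2.92, SE 0.18, adjusted p = 3.4e-06), against 10.4 ± 0.716 in DMSO. GDF15, a stress-induced cytokine, reached 11.4 ± 3.23 FPKM at 0.7 µM (2.95 between the doses). The chemokine CXCL1 was higher at 0.7 than at 0.3 µM (3.35), as was FIBIN (2.80). The microRNA genes MIR3648-1 (4.71) and MIR3648-2 (4.33), near-identical copies, had at most 5 counts in any library at 0.3 µM and lost their calls in limma-voom, at adjusted p = 0.185 and 0.168, the highest over the alternatives. Both also lost them without 0.3 µM replicate 1 or 2, MIR3648-1 at 0.0664 and 0.0564 and MIR3648-2 at 0.122 and 0.112, and MIR3648-2 without 0.3 µM replicate 3 (0.0581) or 0.7 µM replicate 2 (0.117) or 3 (0.0872). The call of MIR3648-2 was also lost with no expression filter (0.0609) and with the replicate number as a block (0.0866). EREG (ENSG00000124882, chromosome 4, 74365145 to 74388749), the EGF receptor ligand epiregulin, fell from 62.5 ± 5.11 to 14.0 ± 1.58 FPKM (-2.14, SE 0.09, adjusted p = 4.6e-07). MEOX2 (-2.57), GPR183 (-2.11), the endothelin receptor EDNRB (-1.93) and CSGALNACT1, an enzyme of chondroitin sulfate synthesis (-1.72), were lower at 0.7 µM. FAM47E-STBD1 (-3.68), which overlaps other genes, ranged from 237 to 1815 counts at 0.3 µM and lost its call in limma-voom, at adjusted p = 0.104 (6.0e-04 to 0.104 over the alternatives).

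Of 34 integrated stress response genes, 31 were higher and 0 lower at 0.7 than at 0.3 µM (34 and 0 adjusted over the list alone), with PSAT1 at 1.76 and ASNS at 1.65. Of 27 ER unfolded protein response genes, 15 were higher and 0 lower (16 and 0 adjusted over the list alone), with HERPUD1 at 2.51, HSPA5 2.83-fold higher and XBP1 at 1.15. Of 28 heat shock genes, 24 were higher and 0 lower (25 and 0 adjusted over the list alone), with the co-chaperone DNAJB1 at 1.69 and BAG3 at 1.03. Of 25 cholesterol synthesis genes, 16 were higher and 0 lower (18 and 1 adjusted over the list alone), with FDFT1 at 0.73 and DHCR7 at 0.72. Of 24 NF-kB genes, 8 were higher and 1 lower (11 and 1 adjusted over the list alone), with CXCL2 at 2.51 and NFKBIA at 0.68, and CSF1 lower (-0.20). NRF2 targets did not follow, with 6 higher and 15 lower of 39 (7 and 16 adjusted over the list alone). HMOX1 differed by 0.14 (adjusted p = 0.228), while AKR1C1 (-1.04) and NQO1 (-0.39) were lower at 0.7 µM. Of 33 G2 and M phase genes, 19 were lower and 0 higher (25 and 0 adjusted over the list alone), with CCNA2 at -0.92, and of 32 S phase genes 11 were lower and 2 higher (13 and 3 adjusted over the list alone), CDC6 (0.29) and SLBP (0.48). Of 29 TGF-beta genes, 17 were lower and 1 higher (18 and 1 adjusted over the list alone), with TGFBI at -1.20 and CCN2 at -1.11, and of 25 interferon-stimulated genes 15 were lower and 1 higher (17 and 1 adjusted over the list alone), with OAS2 at -0.93 and IRF1 at 0.63. Of 15 mesenchymal markers, 8 were lower and 0 higher (9 and 0 adjusted over the list alone), with COL3A1 at -1.35.

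The camera calls between the doses for the ATF4 (adjusted p = 3.59e-42), ER (1.82e-10), NF-kB (5.31e-05) and mesenchymal lists (4.38e-06) held at adjusted p = 0.0388 with an estimated correlation, and those for the G2 and M phase (1.75e-13), TGF-beta (3.28e-11) and interferon lists (7.57e-08) at 0.0469. Those for heat shock, cholesterol, NRF2 and S phase genes did not, at adjusted p = 0.0663, 0.0760, 0.115 and 0.115 with an estimated correlation. Mitochondrially encoded mRNAs (11 of 13 lower, 12 adjusted over the list alone), proteasome genes (10 of 33 higher, 17 adjusted over the list alone), autophagy genes (12 higher and 2 lower of 28, 15 and 3 adjusted over the list alone), oligodendrocyte precursor markers (4 of 6 lower, 4 adjusted over the list alone) and neuron markers (2 of 9 higher, 2 adjusted over the list alone) had camera calls that were lost, at adjusted p = 0.115, 0.342, 0.115, 0.137 and 0.115 with an estimated correlation.

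Other lists were also compared between the doses. Higher and lower at 0.7 than at 0.3 µM were 4 and 2 of 24 mitochondrial proteases and chaperones (5 and 3 adjusted over the list alone), 0 and 3 of 43 nuclear OXPHOS genes (0 and 3), 3 and 5 of 26 p53 targets (4 and 6), and 4 and 5 of 29 apoptosis regulators (7 and 6). They were 4 and 4 of 22 JAK-STAT3 genes (5 and 5 adjusted over the list alone), 10 and 9 of 30 immediate early genes (14 and 9), 1 and 0 of 10 metallothionein and zinc transport genes (4 and 0), and 2 and 5 of 28 hypoxia genes (3 and 5). Among 12 astrocyte markers 1 was higher and 3 were lower (1 and 3 adjusted over the list alone), among 8 immune and endothelial markers 1 and 1 (1 and 1), and among 8 histone genes 0 and 1 (0 and 1). Calls among these and earlier lists were lost in settings that included leaving out 0.7 µM replicate 3. There the adjusted p was 0.0826 for GJA1, 0.141 for SOX9, 0.0823 for NDUFA5, 0.0561 for UQCRC2, 0.0993 for MT2A, 0.102 for KDR, 0.0661 for GPR17 and 0.0544 for PSMD12. LONP1 was higher at 0.7 than at 0.3 µM (0.57), as were TNFRSF10B (1.06) and VEGFA (1.28), and HK2 (-1.33), EGLN3 (-0.67), FADD (-0.67) and JAK2 (-0.68) were lower.

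In total, 3379 genes differed between the doses, 1406 higher and 1973 lower at 0.7 µM, and 422 by at least 2-fold, 299 higher and 123 lower. The groups did not overlap for 33.1% of tested genes, against 10% by chance. The number was 2162 without replicate 1 and 2220 without replicate 3 at 0.3 µM.

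The calls against DMSO were then compared. The same direction was called at both doses for 3479 genes, 1721 higher and 1758 lower, against 341 and 385 for independent lists of those sizes. The number was 0 in 20 simulations that drew all 9 libraries anew with no change between groups, which leaves out the effects. Of the genes higher at both, 474 were higher still at 0.7 than at 0.3 µM and 61 were lower, TNFSF18 (-1.33) among them. Of the genes lower at both, 636 were lower still at 0.7 µM and 24 were higher, such as BIRC3 (0.77). Another 27 genes were higher than DMSO at 0.3 µM and lower at 0.7 µM, including EREG, CCN1, CCN2 and TGFBI, and 12 were the reverse, including CXCL1 and FIBIN. Across genes, which are not independent replicates, the log2 fold changes at both doses had a correlation of 0.69 against 0.50 in the simulations and a covariance of 0.79 against 0.17, a difference of 0.62, and 76.3% of genes had the same sign against 66.5%. With 3 DMSO libraries, no division left 2 controls for each dose, so that part of the excess in overlap over independent lists may come from the shared controls.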

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

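Of the tests in this part, the alternatives counted for the genes with opposite calls were chosen after the result was seen.

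Opposite calls were found for 39 genes, which were called higher than DMSO at 1 dose and lower at the other. Each also had a called difference at 0.7 against 0.3 µM. That difference follows from the opposite calls in the same fit and is not further evidence. The 39 genes included CXCL1 (log2 fold change 3.35 between the doses), FIBIN (2.80), EREG (-2.14), TGFBI (-1.20), CCN1 (-1.15), CCN2 (-1.11), IFITM1 (-0.78) and AEN (-0.69). EREG had 52.2 ± 1.91 FPKM in DMSO, 62.5 ± 5.11 at 0.3 µM and 14.0 ± 1.58 at 0.7 µM, and CXCL1 0.669 ± 0.205, 0.205 ± 0.0708 and 2.12 ± 0.294 FPKM.

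For these 39 genes, the library that stood apart was argued against as the source, since 92.3% remained called in opposite directions without 0.7 µM replicate 1. With library size alone, which shifted the median gene by -0.07 at 0.3 µM and -0.08 at 0.7 µM, all 39 kept opposite signs. Of the calls, 53.8% remained, against 97.4% with RLE factors and all with DESeq2, so those that were lost cannot be told apart from a shift of scale. The number of genes with opposite calls was 22, 23 and 22 without DMSO replicate 1, 2 or 3, 21 without 0.3 µM replicate 1, and 91 and 61 without 0.7 µM replicate 1 or 2. A response that turns with dose is an untested candidate explanation for the larger differences, such as EREG.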

How the results depend on the processing

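Counts divided by 4 and the alternatives for genes with opposite calls were chosen after the data were seen. No call of a named gene and no list call reversed under the alternatives run for them. Of 330 calls of named genes in a comparison, 309 kept their call and direction under all 19 settings that gave a value, and 21 lost the call under at least 1. Most of these genes were chosen by size or p in the main fit, so this share does not hold for calls at large. With 1 library left out, the fewest main calls made again were 2992 of 4189 at 0.3 µM, 5925 of 7281 at 0.7 µM and 2110 of 3379 between the doses. With a minimum absolute log2 fold change of 1, the counts were 787, 1963 and 422 for 0.3 µM, 0.7 µM and 0.7 against 0.3 µM, and 615 at both doses, since small changes are removed by construction. Leaving out 1 library in turn gave 3061 to 5449, 6085 to 7563, 2162 to 3680 and 2621 to 4376, the highest in each case without 0.7 µM replicate 1. Fits of only the 6 libraries compared gave 5495, 6603, 2564 and 3953. With an estimated correlation, 4 of 15, 9 of 15 and 7 of 16 camera calls remained. No list changed its call with RLE factors. The number of genes with opposite calls at the doses was 21 to 91 with 1 library left out, 60 on log2(FPKM + 1) and 73 with only the 6 libraries compared, against 39, and the cause was not tested. The replicate numbers did not pair the libraries: same-numbered libraries had correlations of their deviations between -0.0394 and 0.0154, and 3 of 9 libraries correlated best with 1 of their own number. The correlations of differently numbered libraries ran from -0.0244 to 0.0443. With the replicate block the counts were 3634, 6695, 2780 and 3048 at both doses, and 1 list call was lost. List directions near 0 turned with the scaling, as for the mitochondrial proteases and nuclear OXPHOS genes, where library size alone shifted the median gene by -0.07 at 0.3 µM and -0.08 at 0.7 µM. In simulations with these depths and dispersions, 55.8 to 59.2% of log2 changes of 1 were recovered. Far fewer genes changed there than were called in the data, so recovery in the data may differ. With no filter beyond 1 count, 33510 genes were tested instead of 21026 and 3559, 6468 and 2733 changed.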

Other observations

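The tests with the level of the olfactory receptor genes and without 3 of them, and those on scaling and position of the mitochondrial RNAs, and the ontology tests, were chosen after the result was seen, and the matching and limits of the tests on abundance, on RNAs without poly(A) tails and on position were changed after first values had been seen.

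Terms of the gene ontology were tested over all tested genes with terms, list members included. Among genes higher at both doses, terms for regulation of the cellular response to heat (16 genes against 3.52 by chance, adjusted p = 1.2e-04), ubiquitin protein ligase activity (36 against 18.1, adjusted p = 0.0080), amino acid transport (13 against 3.88, adjusted p = 0.0093), transcription repressor activity (28 against 11.3, adjusted p = 0.0012), transferrin transport (9 against 2.40, adjusted p = 0.0316) and phagosome acidification (8 against 1.94, adjusted p = 0.0316) were enriched. Among genes lower at both doses, DNA replication was enriched with 47 genes against 14.5 (adjusted p = 2.8e-11), besides DNA helicase activity with 15 against 4.76 (adjusted p = 0.0023) and GTPase activator activity with 49 (adjusted p = 2.8e-05). Genes lower at 0.7 than at 0.3 µM were enriched for ribosome biogenesis (30 against 11.4, adjusted p = 1.1e-04), rRNA processing (40 against 19.2, adjusted p = 5.8e-04) and RNA helicase activity (22 against 7.51, adjusted p = 3.8e-04), and genes higher for aminoacyl-tRNA ligases (11 against 2.91, adjusted p = 0.0094) and transaminases (7 against 1.24, adjusted p = 0.0102). These are one-sided Fisher's exact tests adjusted over 1513 terms, in which genes are not independent.

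Long non-coding genes were called higher far more often than lower at 0.7 µM (548 and 108, or 83.5% higher, against 42.8% of coding calls) and at 0.3 µM (216 and 54). Readthrough from an expressed coding gene ending within 10 kb upstream was argued against as the whole source. Such a gene was found for 9.27% of risen and 13.6% of uncalled non-coding genes (odds ratio 0.65, 0.47 to 0.89). The odds ratio for a gene starting within 10 kb downstream was also 0.65 (0.41 to 1.02), so the lower share was not particular to the upstream side. Readthrough over longer distances, or into non-coding genes that overlap a coding gene on their own strand, was not tested. Genomic DNA in the 0.7 µM libraries met its test, with summed olfactory receptor counts higher by 0.80 on the log2 scale and no overlap with DMSO (0.64, also with no overlap, without the 3 genes that held 51.3% of these counts), and stays open: the median FPKM rise of risen non-coding genes was 9.30 times (6.96 to 16.0 over libraries) the mean rise of the receptor genes, but those were chosen because they rose, and for all 3872 tested non-coding genes it was 0.874 times that mean and 8.53 times the receptor median. Low abundance stays open, since 60.9% of calls of coding genes matched on mean count were higher, against 83.1% (difference 22.3 points, 17.4 to 27.0), and so do reads of the other strand, since 36.4% (30.3 to 43.0, Wilson) of all 217 risen antisense genes, or 79 of the 173 with a tested coding partner, lay over a coding gene that rose, against 18.3% of all tested coding genes. A change in transcription or decay of non-coding RNA was not tested.

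Mitochondrial mRNAs fell while mitochondrial rRNAs rose, so that the log2 ratio of their counts within a library was 2.83 ± 0.0269 in DMSO, 2.33 ± 0.0387 at 0.3 µM and 1.98 ± 0.0309 at 0.7 µM (SD, n = 3). Scaling of the libraries was argued against by the difference of -0.84 in this ratio at 0.7 µM, which no scaling can move. A steady loss with distance from the heavy-strand promoter among the mRNAs was argued against by a Spearman correlation with position. It was 0.042 over 12 heavy-strand mRNAs (-0.140 to 0.140 with a library left out), which are not independent. The rRNA genes, which start before all of these mRNAs, were not in this test, so it cannot decide on a loss between the rRNAs and the mRNAs. Weaker selection of polyadenylated RNA stays open, since the 4 tested small RNAs without poly(A) tails had a median log2 fold change of 0.39 (-0.83 to 1.15), and 47 with small nucleolar RNAs, scaRNAs and TERC 0.13 (-0.19 to 0.58), and cannot decide it. A fall of mitochondrial mRNA stability, which the design does not separate from lower transcription, is a candidate explanation that was not tested.

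Other groupings of the libraries were compared. Among the 10 ways to divide the 6 libraries of a comparison into groups of 3, the real one gave 4189, 7281 and 3379 genes and the highest other 0, 1 and 1. Each other grouping mixed libraries of both groups, so that the effects entered the spread and lowered its number of calls. With 10 groupings, a share under 0.05 cannot be reached, so these counts do not decide on chance.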
